A study of Lactiplantibacillus plantarum with 12 samples.

How the data were processed

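The study used 2-colour oligonucleotide arrays of Lactiplantibacillus plantarum WCFS1, with 1 RNA extract labelled with Cy3 and another with Cy5 on each of 12 arrays. Of these, 8 arrays carried a control and a folate culture, 4 with each dye orientation, and 4 carried 2 cultures of 1 strain. Dyes and cultures were taken from the labels. The labels name no slide, so slide numbers were inferred from the image locations in the file headers. Per the file headers, the images were quantified with ImaGene 5.6.0 and each deposited scanner file holds the spot intensity and the local background intensity of 1 channel on a linear scale, not corrected or normalized. The deposited value table holds log2 ratios. Set against the scanner readings of 10 arrays, each column equalled log2 of the Cy3 over the Cy5 median spot signal with no background correction and no centring (largest difference 5.00e-14, r = 1), so scale, centring and direction of these columns are known. The column medians were 0.44, -0.31, 0.31, -0.35, 0.36, -0.29, 0.07, 0.10, 0.17, 0.27, 0.09 and -0.23. The submitters' processing notes name limma, with no version.

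The scanner files of 2 arrays, those with folate culture 3, name the probes of another array design: they hold 0 probes of this strain's genes and correlate with their value table columns at -0.0078 and -0.0047. They were not used. The design fixed before the data were examined had 12 arrays and 8 cultures. The fit reported here therefore has 10 arrays and 7 cultures, 4 control and 3 folate, and the value table with 12 arrays and 8 cultures is an alternative. The value table columns of those 2 arrays correlate with that of control culture 1 against folate culture 1 at 0.87 and -0.80. This does not settle their strain labels, since the array of control cultures 2 and 4 correlated with the same column at 0.85 and that of control culture 4 against folate culture 4 at 0.43. The table has none of the 19 folate cluster spots.

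Intensities (spot median) were background corrected with normexp and an offset of 50, control spots were given weight 0, and log2 ratios were normalized within each array by loess in limma 3.58.1 (R 4.3.3). Spots marked empty or poor in the files were left out. The marks fell on bright spots: 31.6 to 46.0% of the brightest 5% of gene probes were marked poor, against 1.53 to 2.71% of the rest. Of 190 readings of the folate cluster 147 were marked, so the cluster was kept with its marks, an exception decided after seeing the data. Spots of a probe and then probes of a gene were averaged, and the median of probes is an alternative. Saturated spots (65535) were kept. A reading counted as above background when it exceeded the local background by more than 2 of its SDs.

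The culture is the replicate, since the labels describe independent cultures and each RNA sits on 2 to 4 arrays. In stage 1, least squares per gene turned the log2 ratios of the 10 arrays into 1 value per culture, centred over the cultures, with a dye term. In stage 2, limma (lmFit, eBayes) compared 3 folate with 4 control values, 2-sided, with Benjamini-Hochberg adjustment at 0.05. Of 2851 genes 28 had no value for every culture. Gene lists were tested with camera at a preset correlation of 0.01, leaving the folate cluster out of all other lists and lists under 4 tested genes untested. The cluster median was tested by exact permutation. Differences are folate minus control on the log2 scale.

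Gene symbols came from the platform annotation, which gives 1 symbol for 1134 of the table's probes, several for 0 and none for 8454, so 333 genes are named and the others keep their locus tags. It gives no products. The reference gene table at hand belongs to another strain and matched no locus tag. Of the 28 lists fixed beforehand, 18 could be tested, and those of prophage, transposases and sugar transport had no member, since they rested on products or on symbols that no gene here has. Genes without a symbol entered 6 lists by a locus range fixed beforehand: purine, pyrimidine, ATP synthase, fatty acid, capsule and plantaricin. Their function is assumed from the range and not given by the annotation. The genes named were fixed beforehand by rule: the cluster, up to 12 genes per direction with the largest difference among those past the threshold, up to 3 genes of each list with the smallest p, and 6 loci on either side of the cluster. The native plasmid groups were chosen after their values were seen.

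The culture numbers of the labels are shared between strains. The RNA names are W2, W3R, W3L and Warno for control cultures 1 to 4. Those of folate cultures 1, 2 and 4 are Hy2, Hy1L and Hyparno. Both cultures of number 4 share an ending and control cultures 2 and 3 share a stem, and what this stands for was not tested. Deviations from the strain means correlated across genes at 0.25, 0.12 and 0.41 for cultures 1, 2 and 4, so the numbers count as pairing these cultures by the rule that every pair exceeds 0.1. Cultures of different number ranged from -0.32 to 0.18, and control culture 2 correlated more with folate culture 1 (0.15) than with folate culture 2. In the value table, with 4 pairs, the values were -0.14, 0.08, 0.07 and 0.33 and did not. Cultures 1, 2 and 4 of the 2 strains also met on an array by number, as did control culture 3 with each folate culture (0.18, 0.14 and -0.29). Pairing by number and a shared array are thus not told apart. The labels do not say what a number shares. A replicate block is therefore reported beside the counts it changes. Control culture 3 has no folate culture of its number in that fit, so it adds nothing to the difference there.

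The 2 stages were tested on simulated arrays of 2823 genes with the culture and array spread of the comparison of 4 control with 3 folate cultures. Of genes changed by 0.5, 1 and 2 on the log2 scale, 74.6%, 98.5% and 100% were recovered, with 9 false calls among 2623 unchanged genes. The simulated spread was drawn independently for each gene and was alike in both strains. It held no signal shared across genes, so the number of false calls does not carry over to the real arrays. Alternatives covered background, normalization, dim genes, probe summary, marked spots, dye term, arrays as replicates, arrays with both strains only, a random culture effect, the variance prior, pairing, each culture left out, and the set test. Settings added after seeing the data covered the spot mean, the low-end signal, loess on the value table, the slide as a block, control cultures 1 to 3 left out, the brighter genes alone, and an estimated correlation in the set test of 4 of the fits. Figures were drawn with matplotlib in Python.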

Results

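Lactiplantibacillus plantarum WCFS1 was compared in 2 forms: a control strain with the plasmid pNZ7021 and a folate strain with pNZ7026, a plasmid that carries the folate gene cluster lp_3294 to lp_3299. Both were grown in chemostats at a growth rate of 0.35 per h with 25 mM glucose and 10 mg/l para-aminobenzoic acid, a building block of folate. The labels give 4 independent cultures of each strain, and their RNA was hybridised in pairs to 12 arrays with 2 dyes. Scanner readings of this array design were used from 10 arrays, which hold 7 cultures: control cultures 1 to 4 and folate cultures 1, 2 and 4. Each of these 10 arrays has 10807 spots, of which 9553 are probes for 2851 genes, and 2823 genes could be tested. Folate culture 3 enters only through the deposited value table. The number of arrays and cultures limits the precision.

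The readings of the cultures were not alike at the dim end. The 5th percentile of the background-subtracted gene probes was 310.5 to 509 brightness units in the 8 channels of control cultures 1 to 3, and 99.5 to 187 in the 12 channels of control culture 4 and the folate cultures. Probes made against the opposite strand of a gene (4 spots per array) had channel medians of 615 to 1137 units in control cultures 1 to 3 and of 68.8 to 210.5 in the other channels. Blank spots had a mean signal of 1 unit or less in every culture. This low-end signal thus separated 3 of the 4 control cultures from all others, with both antisense medians of control culture 4 (174 and 210.5) above those of every folate channel (up to 138.5), and its values stand beside the gene groups that moved with it. A later fit took it as a covariate, as the 5th percentile over the median. That was 0.17 to 0.20 in the folate and 0.25 to 0.45 in the control cultures. The ranges do not overlap, so that fit cannot part the strain from the low-end signal. A call lost or turned there therefore decides for neither.

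The folate cluster was far higher in the folate strain. All 6 genes rose, by 4.57 to 4.90 on the log2 scale, and the median difference was 4.77, a 27.3-fold higher level. The gene with the greatest difference was lp_3294, at 4.90 ± 0.31 (SE, 4 control and 3 folate cultures), and the smallest was that of lp_3299, at 4.57 ± 0.34. The cluster median per culture was -2.05 ± 0.63 (SD, n = 4) in the control strain and 2.73 ± 0.22 (SD, n = 3) in the folate strain. The 2 strains did not overlap, and an exact 2-sided permutation test over 35 assignments gave p = 0.0286, the smallest p that 4 against 3 cultures allow. The limma adjusted p of the 6 genes was at most 0.000414. All 6 arrays that carried both strains showed the direction of the labels, with medians of 3.97 to 5.97. Of the 2 slides with 2 such arrays each, slide 1 had a mean of 4.42 and slide 2 of 4.76, slides 4 and 5 had 1 such array each, and with the slide as a block the difference was 4.76. In the folate channels 18 of 190 cluster readings were saturated, so the folds of lp_3294, lp_3295, lp_3296 and lp_3299 are low estimates and the order of the 6 genes is not settled. The control cultures spread from -1.18 in control culture 1 to -2.63 in control culture 4, in the order of their low-end signal. The size of the difference moved with them: it was 5.97 without control cultures 1 to 3, where 1 control culture remains, and 6.07 with the low-end signal as a covariate, both chosen after seeing the data.

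**Figure D1:**
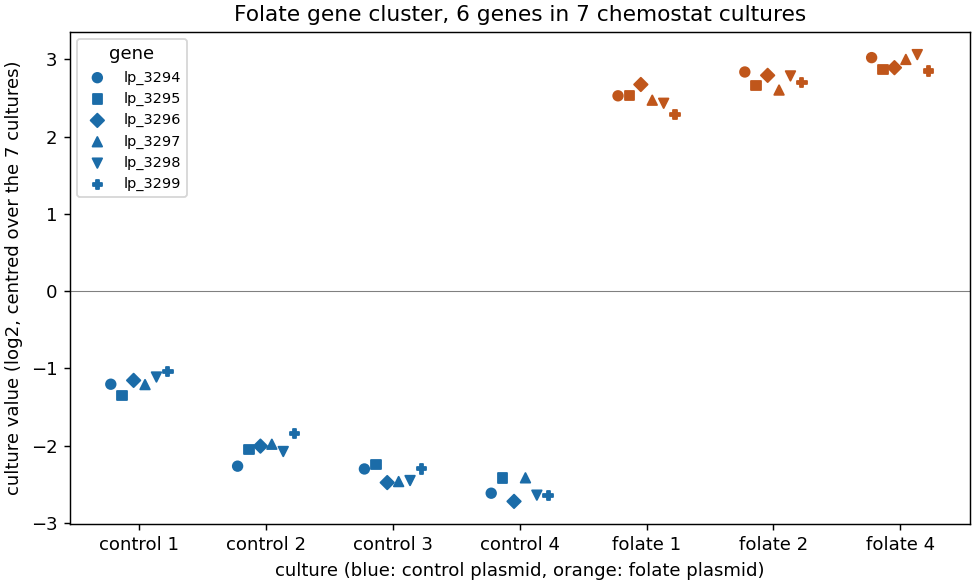
Culture values (log2, centred over the 7 cultures) of the 6 folate cluster genes, 1 marker shape per gene, with control cultures in blue and folate cultures in orange. The control cultures have cluster medians of -2.63 to -1.18, and those of the folate cultures lie above 0, at up to 2.95.

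The chromosomal neighbours of the cluster, lp_3288 to lp_3293 and lp_3300 to lp_3305, did not follow it. Of the 9 tested neighbours, none passed the threshold in either direction, over all genes or adjusted over the list alone, and their median difference was -0.04. The nearest ones were lp_3293, at -0.07 ± 0.08 (SE), and lp_3301, at 0.01 ± 0.10. The lowest p among them was that of lp_3302, at -0.37 ± 0.10 with an adjusted p of 0.054. As a list they did not pass (camera, adjusted p = 0.40; adjusted p = 0.69 with an estimated correlation). After median centring without loess, lp_3293 (0.28, adjusted p = 0.043) and lp_3291 (-0.54, adjusted p = 0.030) passed in limma, both with their direction turned, and with the low-end covariate lp_3293 was at 0.21 and lp_3301 at -0.17.

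Outside the cluster, the largest increases were those of the native plasmid genes lp_p2_02 and lp_p2_01 (log2 difference 1.95 ± 0.37 SE) and of the chromosomal genes lp_3679 (1.49 ± 0.15, 2.81-fold) and lp_3414 (1.29 ± 0.22, 2.45-fold), with lp_2447, lp_2440, lp_3413, purH, lp_3677, lp_0244, lp_2445 and purD between 0.75 and 1.14. Without control cultures 1 to 3, several of these were far smaller, with lp_2447 at 0.14, lp_2440 at 0.30, lp_2445 at 0.35 and purH at 0.49, and with the low-end covariate they were at 0.34, 0.53, 0.59 and 0.52 and lp_0244 at 0.48. The size for lp_p2_02 is not settled, since its probe was above background in all 10 folate readings and in 1 of the 10 control readings. It was 3.47 with the background correction used, 4.40 with an offset of 10, 1.21 with no background correction and 1.38 in the value table. The largest decreases were those of genes of native plasmid p3, lp_p3_08 (-1.71 ± 0.37, 3.28-fold lower) and lp_p3_05 (-1.71 ± 0.39) first, and of adhE (lp_3662; -1.43 ± 0.31, 2.69-fold lower), a bifunctional alcohol and acetaldehyde dehydrogenase. The remaining 9 of the 12 largest decreases were lp_p3_10, lp_p3_11, lp_p3_18, lp_p3_09, lp_p3_15, lp_p3_16, lp_p3_22, lp_p3_23 and lp_p3_28, at -1.41 to -1.27. With the low-end signal as a covariate, none of the p2 and p3 genes passed, lp_p2_01 was at 0.30, and the direction of lp_p3_08 (0.071), lp_p3_05 (0.17), lp_p3_09 (0.15), lp_p3_15 (0.18), lp_p3_16 (0.13) and lp_p3_28 (0.0042) turned. In limma, with Benjamini-Hochberg adjustment over 2823 genes, 203 genes outside the cluster passed, 87 higher and 116 lower in the folate strain, with a median size of 0.45 on the log2 scale, and 24 of them differed by over 2-fold. The count including the cluster was 209. The culture values of all 209 did not overlap between the strains, but neither did those of 887 of the 2823 genes, where chance gives 5.71%. The count of 209 fell to 10, 11 and 8 without control cultures 1, 2 and 3 and to 8, 7 and 7 without folate cultures 1, 2 and 4, and rose to 1119 without control culture 4. With the culture number as a replicate block it was 15, and it was 8 without control cultures 1 to 3 and 10 with the low-end covariate, both chosen after seeing the data. The value table, with 8 cultures and no cluster genes, gave 0 genes past the threshold in limma and 1390 at an unadjusted p under 0.05, where the 10 arrays gave 1025. Without control culture 1, 2 or 3 or a folate culture, all 208 or 209 of the calls tested kept their sign. Of them 189 to 209 kept an unadjusted p under 0.05 in limma, so those falls lay largely at the adjusted threshold. The calls were chosen from these same cultures and do not overlap between the strains. Their sign was thus nearly fixed, and neither number is separate support for the calls. With the covariate 189 of 209 kept their sign and 41 such a p.

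Single genes differed in how they stood against these settings. The gene lp_3679 passed in all 7 fits that left out 1 culture and had an adjusted p of 0.0030 with all cultures. Its value was -0.84 to -0.40 in the 4 control cultures and 0.64 to 1.18 in the 3 folate cultures. No other gene outside the cluster passed in all 7. The genes lp_p2_02, lp_0244 (0.77 ± 0.09) and lp_0329 (-0.70), the last of which lies outside the rule for named genes and was chosen after its values were seen, each passed in 3 of the 7. Without control culture 4, 205 of the 209 calls passed in limma. Of the 203 genes, 192 passed in 1 of the 7 fits. The genes purH, purD, glyA, argS, fba, argJ, adhE, lp_2104 and lp_3414 were among these. With the replicate block 9 genes outside the cluster passed in limma. Among them were lp_3679 (adjusted p = 0.035), lp_p2_02 (0.0050), lp_0244 (0.047) and adhE (0.047), and purH and purD (both 0.071) did not pass. The value of adhE was above 0.9 in control cultures 2 (0.97) and 3 (1.31), and 0.22 and -0.05 in control cultures 1 and 4, against -1.09 to -0.66 in the folate cultures.

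Genes of the native plasmids moved apart. Of 38 tested genes of plasmid p3, 18 fell, none rose and 20 did not pass, with a median difference of -0.93. With the culture number as a replicate block, only 2 genes passed as lower in limma, adhE among them. Most of these 18 calls are thus lost with the block, where all 209 calls kept their sign and an unadjusted p under 0.05 in limma. The calls were chosen from the same cultures, so this is no separate support. Control culture 3 adds nothing to the difference in that fit, so the losses cannot be laid to pairing alone. Both tested genes of plasmid p2 rose, and of the 2 tested genes of plasmid p1 none passed. The median of the p3 genes was 0.82 and 0.83 in control cultures 1 and 2, 0.26 in control culture 3, -0.23 in control culture 4 and -0.63 to -0.44 in the folate cultures. They were thus highest in the 2 cultures with the highest low-end signal. Without control cultures 1 to 3 the median p3 difference was -0.38 and that of p2 was 1.23. With the low-end signal as a covariate the p3 median turned to 0.13, with 26 of the 38 genes above 0 and none past the threshold, and that of p2 was 1.21. Since the covariate does not overlap between the strains, this turn does not decide, and the p3 genes have no settled direction.

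**Figure D2:**
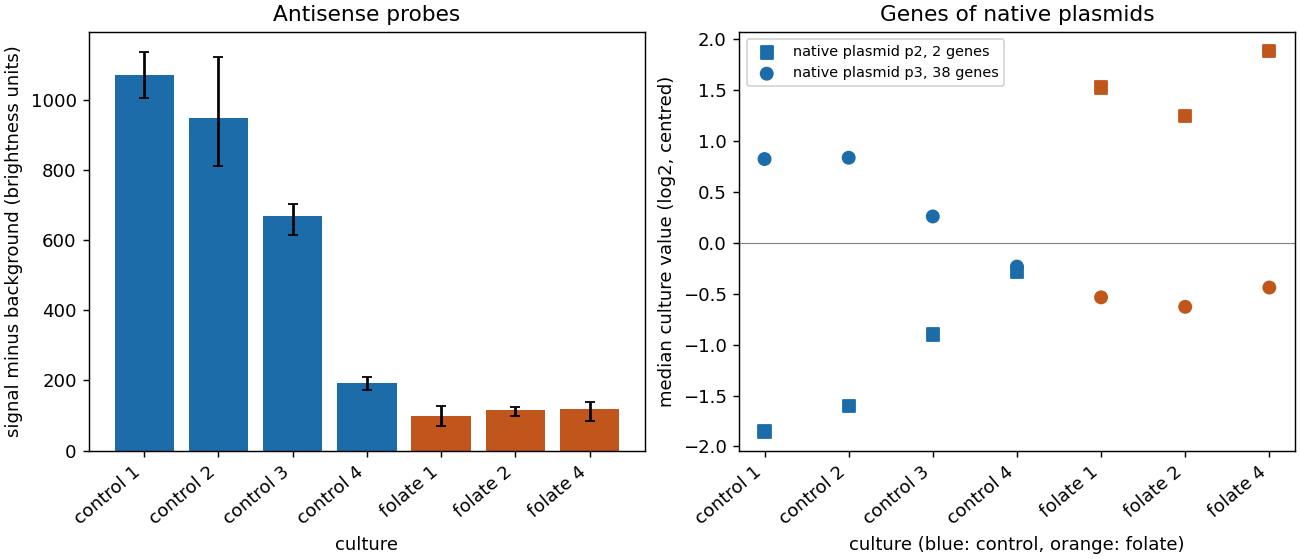
Left, background-subtracted signal of antisense probes in brightness units, with bars for the mean of a culture's channel medians and whiskers for its lowest and highest channel. Right, median culture values (log2, centred) of native plasmid genes. Control cultures 1 to 3 have antisense means of 669 to 1072 units against 192 in control culture 4 and 98.7 to 118 in the folate cultures, and the p3 medians fall from 0.83 in control culture 2 to -0.63 in folate culture 2.

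Genes of purine biosynthesis, the pathway that makes the purine nucleotides and with them GTP, the precursor of folate, were higher in the folate strain. Of 15 tested members, 2 rose past the threshold over all genes, 13 did not, and 11 rose when p-values were adjusted over the list alone. The bifunctional purH (lp_2720) was at 0.85 ± 0.17 (SE, adjusted p = 0.046) and purD (lp_2719) at 0.75 ± 0.14 (adjusted p = 0.045). Neighbouring genes that did not pass had similar values, such as purS at 0.79 ± 0.23 and purF at 0.60 ± 0.16 (adjusted p = 0.053). Of the separate genes, purB (lp_3269) was at 0.35 ± 0.11, while guaA (0.11 ± 0.08), guaB (0.10 ± 0.08) and purR (-0.12 ± 0.07) lay near 0. The list median was 0.60, and camera placed the list above the other genes with an adjusted p of 0.000163. That call is lost with an estimated correlation (adjusted p = 0.69) and with the low-end signal as a covariate (list median 0.34, adjusted p = 0.10), a setting chosen after seeing the data. The list also did not pass in fry (adjusted p = 0.14). That set test asks whether the genes of a list differ at all, where camera sets them against the other genes. The within-slide medians were 0.87 on slide 1, 0.44 on slide 2 and 0.50 and 1.05 on the single arrays of slides 4 and 5, and the fit with the slide as a block gave 0.64. Over the list, control culture 4 lay 0.36 above the mean of control cultures 1 to 3, on the side of the folate cultures. In purS, purM, purQ and purN it lay at 0.19, 0.09, 0.09 and 0.10, above folate culture 2 at 0.04, 0.04, -0.05 and 0.03. It also lay above folate culture 2 in purC (0.0283 against 0.0059), lp_2728 (0.0545 against 0.002) and purE (0.0645 against -0.0097). In purH, purD, purF, purL and purB the cultures of the strains did not overlap, and in the other members of the 15 they did. Over all genes, 887 of 2823 did not overlap, so this does not set the list apart.

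**Figure D3:**
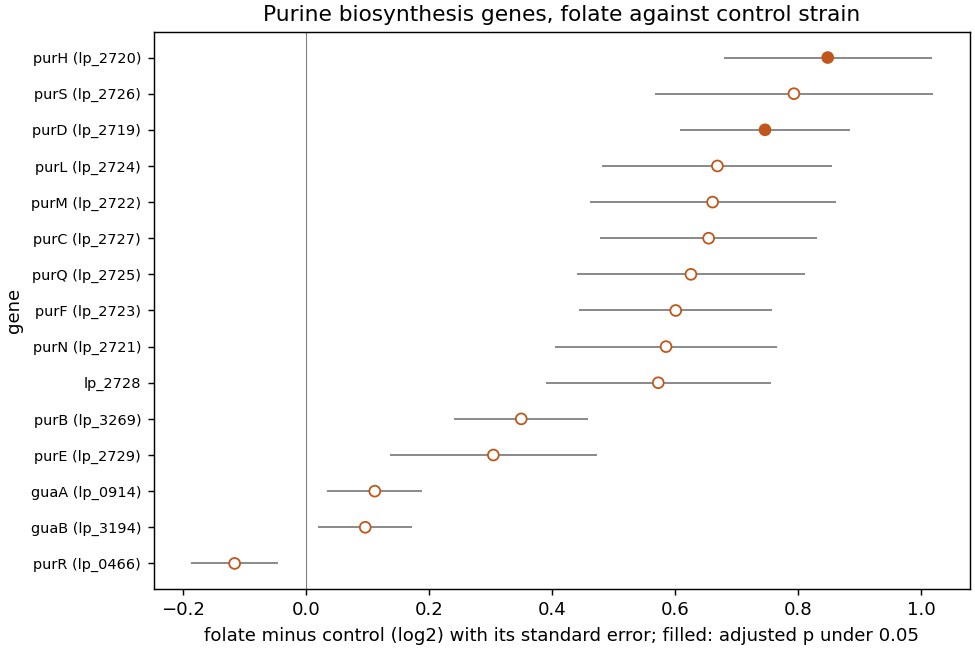
Log2 differences, folate minus control strain, of the 15 purine biosynthesis genes with their standard errors, with filled points for adjusted p under 0.05. The genes purH (0.85) and purD (0.75) are filled, and guaA, guaB and purR lie between -0.12 and 0.11.

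Other genes that use or make folate were few on the array by name. Of the 3 tested, glyA (lp_2375), which encodes serine hydroxymethyltransferase and loads the 1-carbon unit onto tetrahydrofolate, rose by 0.44 ± 0.09 (SE, adjusted p = 0.046). The methionine synthase gene metE was at -0.51 ± 0.15 and passed only when adjusted over the list alone (1 higher, 1 lower), and fmt was at 0.07 ± 0.09. With the low-end signal as a covariate metE turned to 0.18, so its direction is not settled, and glyA was at 0.16 (adjusted p = 0.67). In glyA, control culture 4 (0.03) lay above the other control cultures (-0.31 to -0.23), and in metE it lay at -0.22 against 0.23 to 0.43 in the others. The single riboflavin gene with a symbol, ribH, was at 0.09 ± 0.11.

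Genes of the SOS response and DNA repair were the other list past the threshold. None of its 12 members passed singly, over all genes or adjusted over the list alone, and the list median was 0.13 (adjusted p = 0.028 in camera and 0.023 in fry). The call is lost with an estimated correlation (adjusted p = 0.69), without control culture 4 (adjusted p = 0.10), without folate culture 2 (adjusted p = 0.064), without control cultures 1 to 3 (adjusted p = 0.25) and with the low-end covariate (adjusted p = 0.69). The recombinase gene recA was at 0.29 ± 0.09 (SE), recN at 0.34 ± 0.12 and the mismatch repair gene mutS at 0.17 ± 0.06. The direction of recN turned without control cultures 1 to 3 (-0.0065) and with the covariate (-0.13). Over the list, control culture 4 lay 0.12 above control cultures 1 to 3.

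Lists of amino acid synthesis and of the envelope did not pass as lists in the reported fit, but several did in other settings. In arginine and carbamoyl phosphate synthesis, argJ (lp_0529) was lower in the folate strain (adjusted p = 0.045), the other 5 of 6 members did not pass, and 3 were lower when adjusted over the list alone. The size for argJ is not settled, since 14 of 30 folate readings were above background against 29 of 30 control readings: it was -0.42 with the background correction used, -0.82 with the low-end signal subtracted, -0.19 with it as a covariate and -0.03 in the value table after loess. The list median was -0.29 (camera, adjusted p = 0.13), and in fry the list passed (adjusted p = 0.023). Of the 2 genes named carB, lp_0526 was at -0.84 ± 0.22 (SE) and turned to 0.16 with the covariate, and lp_2700 was at -0.14 ± 0.13. Over that list control culture 4 lay -0.17 from control cultures 1 to 3. None of 8 histidine genes, 10 genes of aromatic amino acids and chorismate or 3 of branched-chain amino acids and peptide uptake passed. The last 3 were the peptidase genes pepI, pepV and pepT, so that list held no uptake gene. The 2 genes named aroE were at -0.34 ± 0.10 (lp_3494, at 0.02 with the covariate) and -0.12 ± 0.07 (lp_2035). The list of methionine, cysteine and serine held 2 genes, metK and serC, and none of cysteine synthesis. Of these, serC (-0.41 ± 0.11) passed only when adjusted over the list alone. It was at 0.0069 without control cultures 1 to 3 and 0.049 with the covariate. The camera adjusted p was 0.53 for histidine and 0.32 for aromatic amino acids. The 48 genes of the capsule and surface polysaccharide list have no symbol and were listed by locus range alone. Of them lp_2104 was lower (adjusted p = 0.048 in limma). Its size is not settled, since 1 of 10 folate readings was above background. It was at -0.34, at -0.85 with the low-end signal subtracted and at -0.03 in the value table after loess. The list median was -0.04 (camera, adjusted p = 0.96). None of 11 cell wall genes (median 0.12, camera adjusted p = 0.16) and none of 22 plantaricin genes (median -0.03, adjusted p = 0.53) passed. Most of the 22 have no symbol and were listed by locus range. In the value table, which has no loess, the lists of arginine (median -0.25, adjusted p = 0.031), histidine (-0.18, 0.020), cell wall (0.19, 0.00098) and plantaricin (-0.16, 0.013) passed in camera. With median centring of the scanner values these passed too, with arginine at -0.96, as did capsule (-0.34, adjusted p = 0.012). With the low-end covariate histidine turned to 0.24 (adjusted p = 0.034), and without control cultures 1 to 3 plantaricin passed at -0.097 (adjusted p = 0.044). With an estimated correlation none of these calls holds (adjusted p of histidine 0.44, 0.49 and 0.77, and 0.80 for plantaricin without those cultures).

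The result for lists of growth and central metabolism depended on the loess step. None of the 44 tested ribosomal protein genes passed, and their median was -0.02 (camera, adjusted p = 0.98). Among 12 tRNA ligase genes, argS rose by 0.34 ± 0.07 (SE, adjusted p = 0.046), and 11 did not pass (list median 0.09, adjusted p = 0.18). None of 14 genes of translation factors and RNA polymerase (median 0.08, adjusted p = 0.32), 8 of ATP synthase (-0.12, 0.40), 11 of heat shock and Clp (0.06, 0.40), 23 of DNA replication and cell division (0.06, 0.40) or 7 of pyrimidine biosynthesis (-0.13, 0.23) passed. The list of glycolysis and lactate formation held fba, tpiA, pyk, pfkA and eno, and no gene of lactate formation. Its aldolase gene fba (lp_0330) rose by 0.39 ± 0.09 (adjusted p = 0.047 in limma) and the other 4 of 5 did not pass. In camera the list had an adjusted p of 0.30, with eno at 0.25 ± 0.10 and pyk at 0.07 ± 0.06. That list passed in fry (adjusted p = 0.049). The direction of fba is not settled: it was at 0.34 in the value table (adjusted p = 0.33 in limma) and at -0.06 after loess on that table, and with no background correction its adjusted p was 0.069. Of 3 genes of pyruvate dissipation adhE fell, and pta (0.11 ± 0.07) and pdhA (0.15 ± 0.10) did not pass. None of 14 genes of fatty acid biosynthesis, most of them listed by locus range, passed, with a median of -0.19 (camera, adjusted p = 0.086). With the low-end covariate that list passed as lower (-0.32, adjusted p = 0.0026; 0.77 with an estimated correlation). Without loess, after median centring alone, ribosomal proteins (median 0.63, camera adjusted p = 1.71e-07), translation factors and RNA polymerase (0.59, 0.000237), tRNA ligases (0.37, 0.0013), heat shock and Clp (0.59, 0.0013), DNA replication and cell division (0.36, 0.000237) and glycolysis (0.62, 0.033) passed as higher in the folate strain. All of these but glycolysis passed in the value table too, with ribosomal proteins at 0.46 (adjusted p = 5.19e-07). None holds with an estimated correlation (adjusted p of ribosomal proteins 0.49 and 0.42). The directions without loess went with brightness. The mean log2 intensity was 10.5 for tRNA ligases to 13.1 for ribosomal proteins among these lists. It was 8.78 to 9.29 for arginine, histidine, plantaricin and capsule, which were lower. Without loess, an intensity trend and a change of these genes cannot be told apart. With median centring the medians of fatty acid biosynthesis, ATP synthase and pyrimidine biosynthesis were 0.47, 0.52 and 0.14 and eno was at -0.11, so these have no settled direction. The peroxidase gene tpx, the only oxidative stress gene with a symbol, was at 0.12 ± 0.09. With the low-end covariate eno (-0.026), pta (-0.070), pdhA (-0.0038) and tpx (-0.071) lay below 0, and DNA replication and cell division turned to -0.10 (adjusted p = 0.0089; 0.77 with an estimated correlation).

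The spread between cultures of a strain was far smaller than the cluster difference. The median over genes of the SD was 0.12 over the 4 control cultures and 0.07 over the 3 folate cultures. Arrays with 2 cultures of 1 strain gave an SD over genes of the log2 ratio of 0.12 for control cultures 1 and 2, 0.35 for control cultures 2 and 4, 0.25 for folate cultures 1 and 2 and 0.24 for folate cultures 1 and 4. On the array of control cultures 2 and 4, 52 genes outside the cluster differed by over 2-fold, against 0 on that of control cultures 1 and 2. The 6 arrays with both strains had SDs of 0.22 to 0.43, so the array of control cultures 2 and 4 lay within their range. The array of control culture 4 against folate culture 4 had the smallest of the 6, at 0.22.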

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

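The tests of plasmid p3 genes, blank spots and control culture 4, of the position of control culture 4 over the called genes, and both tests of the purine list were chosen after the results were seen. The tests of gene dosage, dye orientation and sample splits were set before their results were seen.

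Antisense probes, which enter no comparison, gave a mean of channel medians of 1072 brightness units in control culture 1, where blank spots gave 0.50. The same low-end signal was raised in control cultures 2 and 3, and in control culture 4 (192 units) it lay above the folate cultures (98.7 to 118) to a lesser degree. Blank spots argue against optical background: their mean differed by -0.26 units between the 2 sets of channels, where the 5th percentile of gene probes differed by 270. The control plasmid as such stays open: the 5th percentile over median of control culture 4 lay at 0.28 on a scale from the folate cultures (0) to control cultures 1 to 3 (1), but this is 1 culture. A candidate explanation is genomic DNA in these RNA preparations, which passed a test of gene dosage for control culture 2 and was not tested for control cultures 1 and 3. On the array of control culture 2 against 4, the ratio of 1387 dimmer chromosomal genes fell with distance from the replication origin, taken to lie at dnaA (lp_0001), with distance read from locus numbers (Spearman rho = -0.34 across genes, which are not independent replicates, where 10000 shuffles gave -0.05 to 0.05). The brighter genes had a rho of -0.35, so a dosage difference in the RNA itself stays open. On that array the 38 genes of native plasmid p3 had a median of 1.07, which restates the culture values that drew attention to them and decides nothing. The 2 tested genes of native plasmid p2 went the other way. Their median was -1.85, -1.60 and -0.90 in control cultures 1 to 3 and -0.29 in control culture 4, and this was not tested.

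Of the 203 genes outside the cluster 99.5% kept their sign in both dye orientations, but they were called from arrays of both, so this share decides nothing on dye effects. The design argues against a dye effect alike on all arrays: the fit has a dye term, and each orientation has 3 arrays with both strains. Without the term all 209 calls kept their sign and 186 passed in limma, but that fit uses the same arrays that gave the calls. Chance cannot be excluded for their number: 2 of the 35 splits of the 7 cultures gave as many genes. The real value was 203 and the highest other was 1209, from the split of control cultures 1 to 3 against the rest, which follows the low-end signal and points to a structure of the samples. Among the 8 splits that part the 3 culture pairs, the real one alone gave this many, and the highest other gave 0, but 8 splits are too few to exclude chance. The low-end signal may account for a large part of the calls, since control culture 4 had a median position of 0.54 over the called genes (0 = folate cultures, 1 = control cultures 1 to 3), 0.73 over the higher and 0.46 over the lower ones. At 0.8 or more lay 44 genes, lp_3679 (1.05), lp_3414 (1.07) and lp_3677 (1.33) among them, and an effect of the folate plasmid on these stays open.

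For the purine genes, a single outlying culture is argued against by the lowest median with 1 culture left out, 0.49. The low-end signal as a cause and an effect of the folate plasmid both stay open. The difference was 0.60 with all cultures, 0.28 without control cultures 1 to 3, where 1 control culture remains (adjusted p = 0.044; 0.80 with an estimated correlation), and 0.34 with the low-end signal as a covariate (adjusted p = 0.10). For the number of lists past the threshold, 2, chance cannot be excluded: 28 of the 35 splits gave as many, and the highest other gave 9.

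A control culture stood far from the other 3 in 6 of 127 values tested, where chance gives about 6.35. The gap to the nearest culture, as a share of the range, was 0.838 for lp_3414 (control culture 1), 0.848 for lp_3288 (control culture 4), 0.835 for eno (control culture 4), 0.854 for pdhA (control culture 2), 0.944 for lp_3291 (control culture 4) and 0.850 for the median of the list of aromatic amino acids and chorismate (control culture 4).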

How the results depend on the processing

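The settings on the spot mean, the low-end signal, loess on the value table, the slide, control cultures 1 to 3, the brighter genes alone and an estimated correlation in other than the reported fit were chosen after seeing the data. The folate cluster kept its direction and stayed past the threshold in every setting that holds it, at 4.24 to 6.07; the value table has no cluster spots. The count of 209 genes past the threshold stayed within 1.5 times for normexp offset 10, scaling between arrays, marked spots kept, no dye term, trend and robust, spot mean and low-end signal subtracted. It was 17 with no background correction, 1057 with median centring only, 64 without the dimmest 25% of genes, 31 with the median of probes, 8 on the 6 arrays with both strains, 1244 with arrays as independent replicates, 704 with generalised least squares and 409 with the slide as a block. Leaving out 1 culture gave 7 to 1119 genes, the highest without control culture 4. It was 8 without control cultures 1 to 3, 10 with the low-end signal as a covariate and 13 for the brighter genes alone, where fewer genes are tested. In the deposited value table limma gave 0 genes with median centring (1390 at an unadjusted p under 0.05) and 0 with loess (866). The cause was not tested except where stated. The share of higher calls was 44.5%, and 36.3% with median centring, 31.8% with scaling, 94.1% with no background correction.

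With the replicate block the count was 15, of which 14 were among the 209, and the lists past the threshold were the same 2. Over list members outside the cluster, 8 passed over all genes and 20 when adjusted over each list alone.

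Lists past the threshold numbered 2. They were 15 with median centring, 13 in the value table, 4 with the low-end covariate and 1 to 4 with 1 culture left out. With an estimated correlation they were 0, also with the covariate, with median centring and in the value table. The set test fry, which does not set a list against the other genes, gave 3. The spread between cultures, 0.10, was 0.0621 with no background correction, 0.15 with median centring and 0.15 on arrays with both strains. Over all called genes, 186 of 209 kept their sign with median centring, 187 of 203 in the value table and 189 of 209 with the covariate. Among the lists and the genes named by rule, past the threshold in either of the 2 settings compared, directions turned with median centring for lp_3291 (-0.54), lp_3293 (0.28), ATP synthase (0.52) and fatty acid biosynthesis (0.47), the last 2 also in the value table (0.41 and 0.43), where fba was at -0.0618 after loess. With the low-end covariate they turned for lp_p3_08 (0.0710), lp_p3_05 (0.17), lp_p3_09 (0.15), lp_p3_15 (0.18), lp_p3_16 (0.13), lp_p3_28 (0.0042), DNA replication and cell division (-0.10) and histidine biosynthesis (0.24). Among named genes past it in neither, 18 turned with median centring, 19 in the value table, 31 with the covariate and 18 without control cultures 1 to 3. With median centring pyrF (lp_2698) was at 0.10, lp_2699 at 0.14 and cysS (lp_0610) at 0.11. Signal was above 2 background SDs for 95.5 to 100% of gene readings per channel, but 137 of the 203 called genes outside the cluster were dimmer than the median gene.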

Other observations

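Some genes and lists stood out once control cultures 1 to 3 were left out or their low-end signal was a covariate, both chosen after seeing the data. Without control cultures 1 to 3, where 1 control and 3 folate cultures remain and the lone control is assumed to vary like the folate cultures, 8 genes passed in limma. They were the 6 cluster genes, lp_2978 (log2 difference 1.18, adjusted p = 0.034) and rpmH (lp_3688a), a ribosomal protein gene (1.28, adjusted p = 0.034). With all cultures lp_2978 was at 0.72 (adjusted p = 0.037) and rpmH at 0.52 ± 0.15 (SE), which did not pass. With the covariate 10 genes passed: the 6 cluster genes, lp_3679 (1.86, adjusted p = 0.043), lp_2978 (1.21, adjusted p = 0.0054), lp_3676 (1.21, adjusted p = 0.047) and lp_2976 (0.70, adjusted p = 0.036). There rpmH was at 0.70 and did not pass (adjusted p = 0.58), and without control cultures 1 to 3 lp_3676 and lp_2976 did not (adjusted p = 0.49 and 0.13).

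The lists that passed in these settings and not in the reported fit were pyrimidine biosynthesis in both, plantaricin without control cultures 1 to 3, and DNA replication and cell division, fatty acid biosynthesis and histidine biosynthesis with the covariate. Genes of pyrimidine biosynthesis had a median of -0.13 with all cultures (camera, adjusted p = 0.23), of -0.37 without control cultures 1 to 3 (adjusted p = 0.0011) and of -0.51 with the covariate (adjusted p = 1.38e-05). Both pyrimidine calls are lost with an estimated correlation (adjusted p = 0.80 and 0.42), and the median was above 0 with median centring (0.14) and in the value table (0.079). Over this list control culture 4 lay 0.38 above the mean of control cultures 1 to 3, so these lower values rest on that culture. In addition, 2 more genes with a symbol passed outside the lists and outside the rule for named genes, and both were lower in the folate strain: thiM (lp_0113), of thiamine salvage, at -0.34 ± 0.06 (SE) and phnX (lp_0711), a phosphonoacetaldehyde hydrolase gene, at -0.90 ± 0.20. In phnX control culture 4 was at -0.10, between control cultures 1 to 3 (0.20 to 0.74) and the folate cultures (-0.55 to -0.47). The phnX difference was -0.31 without control cultures 1 to 3 and 0.011 with the covariate (adjusted p = 0.98), and that of thiM was -0.19 and -0.21 (adjusted p = 0.58 with the covariate).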
